A study of Mus musculus with 6 samples.

How the data were processed

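RNA from sorted TEa cells was sequenced in 6 samples, 3 from allograft and 3 from isograft recipients, and the samples were grouped by their titles. The labels' protocols state that ribosomal RNA was removed from total RNA before the libraries were made. The same protocols describe extraction from ground tissue, whereas the labels give sorted TEa cells as the source, so the steps used on these cells are uncertain. The submitters' processing notes name the genome build mm10 and the tools Subread 2.0.1, featureCounts, DESeq2 1.30.1 and R 4.0.4, without saying what each was used for. The aligner's settings, the annotation release and any filter on genes are not given in the sources used here.

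One table of the whole series was examined. Its column names were compared with every title, description, source name, characteristic and protocol of the samples and with the design text of the series. All 6 columns of values were left out of every computation, because no name matched a sample or a group. Depth per sample, precision, differential expression and gene list tests were for that reason not computed. The tests, the gene lists and the alternative settings had been fixed before the data were examined, and none of them was run. The column of gene identifiers was matched, without version numbers, to the gene identifiers of GENCODE release M21.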

Results

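Gene expression was profiled by RNA sequencing in TEa cells taken from mouse recipients of a heterotopic heart graft. TEa cells are CD4 T cells from a mouse line that carries a transgenic T cell receptor. The cells carried the CD45.2 form of the leukocyte antigen CD45, and the recipients carried CD45.1, so that the transferred cells could be told apart from those of the host. Each recipient received 5000000 TEa cells before transplantation, and the cells were sorted again from the spleen on day 6.

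The design held 2 groups. In the allograft group the donor hearts came from BALB/c mice, which differ from the recipients at the major histocompatibility locus. In the isograft group they came from C57BL/6 mice, which share that locus with the recipients. There were 3 samples in each group, 6 in all, and each was a pool of sorted cells from 3 mice. The comparison named in the design text of the series is between TEa cells from allograft and from isograft recipients. Such a comparison asks which genes differ in expression between the groups.

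No expression value and no difference between the groups is reported here. The deposited table has 6 columns of values, named EA1 to EA6, and 0 of the 6 column names match a title or any other label of the 6 samples. Neither the sample nor the group of any column could therefore be read from its name. The order of the columns was not used to assign them, since no label says that it follows the order of the samples. The levels of individual genes were not used either, because an assignment made from expression would decide in advance the comparison that it was meant to serve.

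The gene identifiers of the table do not depend on that assignment. The table has 13600 rows with 13599 distinct gene identifiers, and 1 identifier is listed more than once. Of the distinct identifiers, 13586 were found in release M21 of the GENCODE mouse annotation and 13 were not. The presence of a gene in the table gives no level in either group.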

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

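The tests of expression fixed before the data were examined were not run under any setting, because no value was taken from the 6 columns. Both alternatives that could be computed were chosen after the table had been seen. When only the number that ends each column name was compared with the number that ends each sample title, 0 of the 6 columns pointed to exactly 1 sample. The numbers of 3 columns were each shared by 2 samples, 1 in each group, and those of the other 3 columns by 0 samples. Because the titles repeat the same numbers in both groups, no column could have pointed to exactly 1 sample. This alternative was therefore no independent check of the match by name. When the match was limited to annotated protein-coding genes on the reference chromosomes, 12294 of the 13599 gene identifiers were found, against 13586 among all annotated genes. No paired analysis was possible because no column was assigned to a sample. The labels give both groups the same replicate numbers but do not say that a number marks a shared batch, day or animal.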
